A study of Danio rerio with 2 samples.

How the data were processed

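RNA sequencing was analysed from 2 libraries of kdrl:GFP+ cells, 1 from morphologically normal siblings and 1 from morphologically mutant embryos of the same zebrafish (Danio rerio) cross at 44 hours post fertilization. kdrl:GFP is a transgene that marks endothelial cells with green fluorescent protein. Per the labels' protocols, embryos were dissociated, GFP+ cells were sorted by flow cytometry, and poly(A) RNA was fragmented, copied with random hexamers and amplified by PCR for Illumina sequencing. The protocol describes no strand-marking step.

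Each deposited table holds one library, with a gene length, an expected count and an FPKM value per Ensembl gene. Per the submitters' processing notes, bcl2fastq 2.16, BWA, Bowtie2 and RSEM were used with the build GRCz10, with no role given for each. The annotation release and any filter are not given in the sources used here. The expected counts were deposited by the authors without normalization. They need not be whole, since reads that match several genes are divided between them, and 74.3% of the sibling and 73.8% of the mutant values were whole to within 0.005. The FPKM values deposited by the authors are per kilobase of effective gene length scaled by the assigned fragments of the library, with no scaling between libraries. Gene length is listed separately in each library as a mean over isoforms, so a shift in isoforms changes FPKM without a change in counts. The tables list only genes with a value above 0 (lowest FPKM 0.01), and a gene listed in one table only was set to 0 in the other.

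The summed expected counts were 5657525 in the sibling and 6169373 in the mutant library. Precision is given as the exact conditional binomial 95% interval of the ratio of rounded expected counts, each divided by its library's sum. These intervals cover counting error only, since PCR copies without molecular identifiers are not independent molecules, and they hold no variation between embryos, sorts or library preparations. With 1 library per group, no test between conditions, standard error or p-value was computed, and no replicate could be left out. All differences compare these 2 libraries.

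The log2 fold of a gene is log2((mutant FPKM + 1)/(sibling FPKM + 1)), which understates the change of genes with low values. A gene was called higher or lower when this value was at least 1 or at most -1, among genes with an FPKM of at least 5 and at least 20 expected counts in at least 1 library. Gene symbols were taken from a table of Ensembl IDs, which named 19802 of the 21699 genes (91.3%). That table gives many zebrafish genes the symbol of their human counterpart without the paralog letter, so 1459 symbols belong to several genes. Symbols are written here in lower case, and where genes share one, the values given are those of the member the rule below picked, and the other genes of that symbol may differ less. No genome coordinates of the build were used.

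Before the data were examined, 36 gene lists were fixed: 35 by symbol, with 969 entries in all, and the cytosolic ribosomal proteins by the form of the symbol. Of the entries, 694 matched a symbol as written and 891 once the symbol without its paralog letter was allowed. This second step was added after the name table was seen. Members with a mean FPKM of at least 1 over the libraries were kept. Counts of list members at least 2-fold higher or lower use this limit alone, so they include genes below the limits for the calls above. The median log2 fold of each list was placed among the medians of 10000 random lists of the same size, drawn from genes matched on mean expression in 20 bins. A list of at least 5 members was said to stand apart when its percentile was under 2.5 or over 97.5, as a description of these libraries. Lists share members, and 13 of the lists hold markers of other cell types that a sort could carry.

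The genes named were chosen by a rule fixed at the same time. It takes gbf1, the 10 highest and 10 lowest genes with a symbol that pass the limits above, up to 4 members of each list with the largest absolute log2 fold, and a set of 17 genes named in advance whatever their values. Of that set, atf4a matched no symbol. Other list members are given as examples of their list and were chosen after their values were seen. Loci with clone-type symbols or none were counted and not named. Of the fixed lists and named genes, 1 list and the genes named through it or with it are not reported here.

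The calculations were tested on simulated libraries built from the real means and totals. These held Poisson counting noise alone, with the same gene lengths in both libraries. They had no variation between embryos, sorts or library preparations, so the shares below are not error rates of the calls in the real data. The interval contained the simulated ratio for 95.7% of 3000 genes. Of unchanged genes, 0.02% of 8039 passed 2-fold. Of genes with a simulated log2 fold of -1.5 or 1.5, 89.8% and 100.0% passed, and 100.0% did so at -2 and at 2. All 20 lists of 20 genes shifted by 0.5 stood apart, as did 7 of 100 unshifted lists.

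Alternatives covered the scaling (centring on the median gene, TPM, edgeR TMM and DESeq2 median-of-ratios factors applied to CPM), the pseudocount, the floor, the fold threshold, and the matching and summary of lists. Rescaling without the 10 highest genes, leaving out genes listed in one table, and matching symbols only as written were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.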

Results

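Transcript levels were measured by RNA sequencing in sorted kdrl:GFP+ cells of zebrafish embryos at 44 hours post fertilization. The cross carried tsu3994, an allele of gbf1, and 1 library each was made from morphologically normal siblings and from mutant embryos. The comparison asks which genes differ between the sorted cells of mutants and siblings. These values are not those of endothelial cells alone. In the sibling library kdrl was at 6.38 FPKM and the globin gene hbae1.2 at 159111, and markers of further cell types were present. There were 20420 genes listed for the sibling library and 20511 for the mutant library, with 5657525 and 6169373 expected counts. An FPKM of at least 1 was reached by 14268 genes in the sibling and 15093 in the mutant library. There are no replicates, so every difference below compares these 2 libraries. Intervals of count ratios cover counting error only. The bootstrap intervals in the closing section cover the spread among members of a list or family. Neither kind holds variation between libraries.

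gbf1, which encodes an exchange factor that activates ARF GTPases at the Golgi, was present in both libraries (ENSDARG00000027016). It stood at 3.44 FPKM in the sibling and 6.13 FPKM in the mutant library, a log2 fold of 0.68. The expected counts were 161 and 364, a ratio per library total of 2.07 (95% counting interval 1.72 to 2.51). The labels do not give the nature of the lesion, so the transcript level does not check the genotype. Of the other large ARF exchange factors, arfgef2 was at 8.82 and 15.4 FPKM. arfgef1 was at 5.99 and 3.62 FPKM, but its counts per library total had a ratio of 0.98 (0.78 to 1.23), because its listed length differed between the tables.

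Across 8641 genes that passed the limits, 667 were at least 2-fold higher and 91 at least 2-fold lower in the mutant library. The exact counting interval lay beyond a ratio of 1 for 659 and 88 of them. Globin genes took much of both libraries: the 10 genes with the highest mean FPKM, of which 6 carry globin symbols and 2 no symbol, held 35.9% of the sibling and 27.7% of the mutant counts. The median log2 fold of expressed genes was 0.27, so most genes stood slightly higher in the mutant library. Count ratios are per library total, so an interval above 1 does not by itself place a gene above the median gene, at 1.2-fold. Centred on that median, the counts were 321 higher and 186 lower, and the share of calls that were higher moved from 88.0% to 63.3%. TMM scaling gave 378 higher and 169 lower (69.1%), median-of-ratios scaling 367 and 175 (67.7%), and rescaling without the 10 highest genes 495 and 143 (77.6%). TPM moved the other way, with 948 higher and 72 lower (92.9%). Counts of list members past 2-fold below use the deposited values, and some members just above the limit fall under it once centred. Among them are arf1 (0.871), eprs1 (0.945), cars1 (0.816), klf2a (0.978) and nid2 (0.981). Over genes with an FPKM of at least 5 in either library, Pearson's r of log2(FPKM + 1) was 0.943 and Spearman's rho 0.885, computed across genes, which are not independent replicates.

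**Figure D1:**
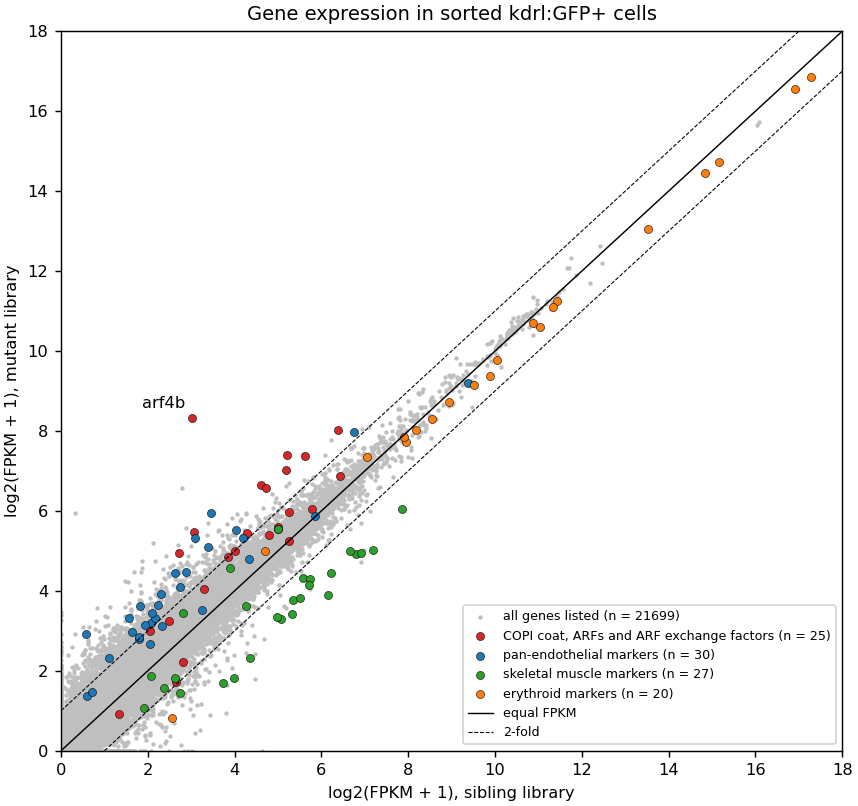
Each point is a gene, with log2(FPKM + 1) in the sibling library on the x axis and in the mutant library on the y axis; coloured points are members of 4 gene lists, the solid line marks equal FPKM and the dashed lines 2-fold. The point for arf4b (7.12 and 317 FPKM) stands apart, most COPI and pan-endothelial genes lie above the line, and most skeletal muscle genes lie below it.

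Genes of the COPI coat, which carries cargo within the Golgi and back to the endoplasmic reticulum (ER), were higher in the mutant library, and so were some of its ARF GTPases. The largest difference was in arf4b, an ARF GTPase, at 7.12 FPKM in the sibling and 317 FPKM in the mutant library (43.3 and 2090 expected counts, ratio 44.6, 33.0 to 61.8). Of 9 genes for coat subunits, 8 were at least 2-fold higher, with a median log2 fold of 1.83. copa went from 36.2 to 168 FPKM (count ratio 4.07, 3.78 to 4.39), copg2 from 23.3 to 99.5, copb1 from 25.5 to 93.6, copb2 from 35.3 to 128 and cope from 48.1 to 165. copz2 was at 5.62 and 29.8 FPKM, and the 2 genes named arcn1 had log2 folds of 2.39 and 1.02, while copz1 was at 26.7 and 41.2. Among the GTPases, arf5 was at 83.1 and 258 FPKM and arf1 at 18.6 and 42.3 (log2 fold 1.14, and 0.87 once centred). With arf4b, these were the 3 of 10 ARF genes past 2-fold. arf4a, arf6b, arf2a, arf2b and arf6 had log2 folds of 0.98, 0.61, 0.45, 0.28 and -0.01. The 2 genes named arf3 were lower at -0.93 (count ratio 0.44, 0.21 to 0.89) and -0.43 (0.59, 0.23 to 1.46). Over the whole list of 25 genes, 11 were at least 2-fold higher and none at least 2-fold lower by the log2 fold on FPKM + 1. By counts, the arf3 gene with a ratio of 0.44 was more than 2-fold lower. The median log2 fold was 0.94, at percentile 100 of random lists, with a range of 0.66 to 1.07 over the scalings. In the same libraries the pan-endothelial markers had a median of 1.22 and the skeletal muscle markers -1.64.

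**Figure D2:**
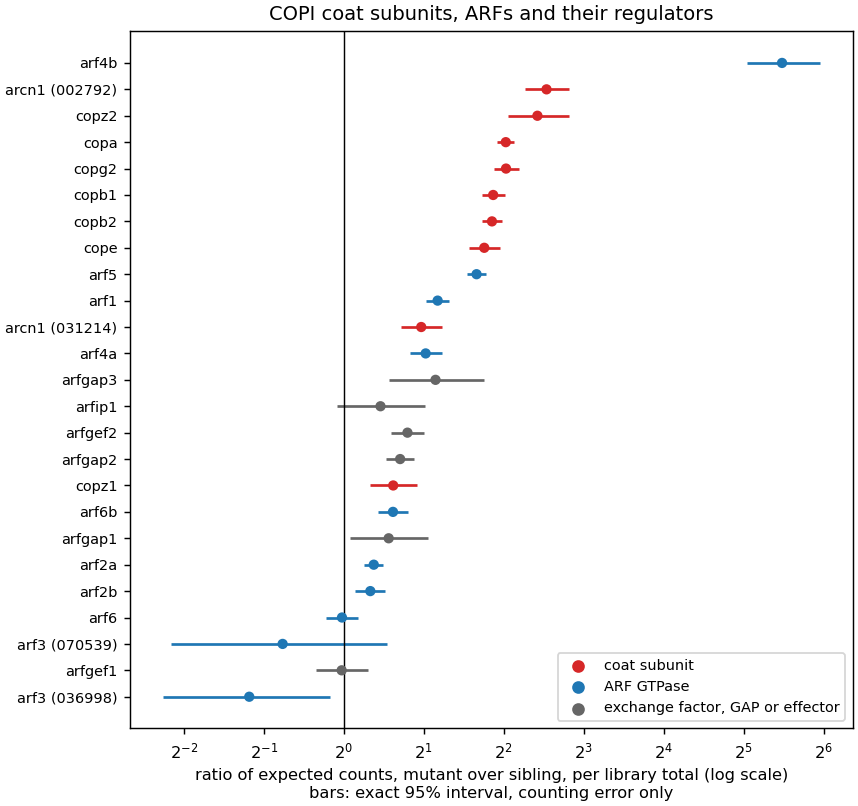
The x axis gives the ratio of expected counts, mutant over sibling, each per library total, on a log scale; points are genes of the COPI list and bars the exact 95% counting intervals, with coat subunits in red, ARF GTPases in blue and their regulators in grey. arf4b lies at 44.6, and the interval of each coat subunit lies above 1.

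The wider ER-to-Golgi machinery was higher as well. Of 37 genes for the COPII coat, cargo receptors and Golgi proteins, 16 were at least 2-fold higher and none at least 2-fold lower, with a median log2 fold of 0.95 at percentile 100 of random lists. The COPII coat genes sec24d (7.02 and 33.7 FPKM) and sec31a (5.45 and 22.8) stood highest. They were followed by creb3l3l, a membrane-bound transcription factor of the CREB3 family (73.0 and 217), and trip11, a golgin (4.41 and 14.6). The KDEL receptors, which return ER proteins from the Golgi, included kdelr2a at 35.3 and 97.8 FPKM and kdelr3 at 4.38 and 13.4, and the cargo receptor lman1 was at 4.35 and 13.6. The golgins golga2 and golga5 had log2 folds of 1.12 and 1.28. The other COPII coat genes did not pass 2-fold: sec24c and sec13 had log2 folds of 0.96 and 0.95, sar1b, sec23a, sec23b and sec24a 0.57, 0.48, 0.41 and 0.37, sec24b and sar1ab 0.11 and 0.06, and sec31b had -0.61 with a count ratio whose interval held 1 (0.88, 0.71 to 1.09). The pan-endothelial, mural and lens medians of 1.22, 1.01 and 1.21 apply beside this list too. So do the skeletal muscle and erythroid medians of -1.64 and -0.25.

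Genes of the ER stress response did not move as a block. Of 35 genes in the ATF4 and CHOP list, 5 were at least 2-fold higher. These were atf5b (4.51 and 20.7 FPKM), ddit3, which encodes the transcription factor CHOP (47.0 and 170, count ratio 3.60, 3.21 to 4.04), eif2ak3, which encodes the ER stress kinase PERK (7.18 and 23.1), phgdh, an enzyme of serine synthesis (17.5 and 45.2), and stc2 (2.15 and 5.56). The others did not pass 2-fold. slc7a5, gars1, asns and psat1 had log2 folds of 0.87, 0.82, 0.74 and 0.64, with intervals above 1, while atf4b was at 263 and 340 FPKM, atf3 at 186 and 196, trib3 at 110 and 137 and chac1 at 614 and 676. The 5 members with a counting interval below 1 were nupr1a at 273 and 160, ppp1r15a at 514 and 403, and ddit4, shmt2 and mthfd2 with log2 folds of -0.42, -0.16 and -0.14. The list median was 0.36 at percentile 99.28, and it did not stand apart under TMM (percentile 92.72), median-of-ratios scaling (percentile 92.72, median 0.00) or unmatched random lists (88.88). None of 29 genes for ER chaperones and ER-associated degradation differed 2-fold by the log2 fold on FPKM + 1. ero1a, at 0.59 and 1.52 FPKM, had a count ratio of 2.23 whose interval held 1 (0.88 to 6.35). hspa5, the main ER chaperone BiP, was at 1842 and 1795 FPKM (count ratio 0.97, 0.95 to 0.99), hsp90b1 at 413 and 369, and pdia4 at 87.1 and 83.6, whereas xbp1 was at 190 and 295 (count ratio 1.55, 1.46 to 1.64). The members dnajb9 (ENSDARG00000052072, 7.24 and 13.1) and dnajc3a (16.0 and 27.9) had the largest log2 folds, 0.77 and 0.76, before derl2 and dnajb11 (0.71 and 0.70). That list had a median of 0.23 at percentile 75.62, below 0 once centred or scaled by TMM or median of ratios. tRNA synthetases and amino acid transporters stood higher (median 0.52, percentile 99.86), with eprs1 and cars1 at least 2-fold higher (log2 folds 1.21 and 1.08) and the transporters slc43a1 and slc6a9 at 0.96 and 0.90. Part of these last folds comes from the listed lengths, with count ratios of 1.54 and 1.32 and log2 folds of 0.34 and 0.12 under TMM. Beside these lists too stand the pan-endothelial and mural medians of 1.22 and 1.01 and the skeletal muscle and erythroid medians of -1.64 and -0.25.

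Most endothelial markers were higher in the mutant library. Of 30 pan-endothelial genes, 21 were at least 2-fold higher and none at least 2-fold lower, with a median log2 fold of 1.22 at percentile 100 of random lists and 0.95 to 1.35 over the scalings. The VEGF receptor gene kdrl, whose promoter drives the transgene, was at 6.38 and 21.3 FPKM (count ratio 3.33, 2.86 to 3.89). cdh5, which encodes VE-cadherin, was at 1.96 and 9.03 FPKM (4.57, 3.58 to 5.91). The transcription factors sox18 (log2 fold 2.48) and fli1 (7.55 and 39.1 FPKM, count ratio 3.77) and the surface proteins myct1 (0.50 and 6.58) and clec14a (5.14 and 20.9) had the largest log2 folds. Of the members that blood cells also express, picked after their values were seen, lmo2 was at 56.7 and 57.6, an abundant gene named aqp1 at 663 and 590, and tal1 at 19.3 and 26.9. In the same libraries the erythroid, epidermal and skeletal muscle markers had medians of -0.25, -0.24 and -1.64, and the mural and lens markers 1.01 and 1.21. These values stand beside the arterial, venous, flow, VEGF, junction and matrix lists below as well.

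Arterial markers had a median log2 fold of 0.77 (percentile 99.98), with 5 of 20 genes at least 2-fold higher, among them the Notch ligand dll4 (9.32 and 41.3 FPKM), aqp8 (2.57 and 21.1) and cxcr4 (11.3 and 44.2), with gja5 at a log2 fold of 1.21. Venous and lymphatic markers had a median of 0.55 (percentile 98.43), with 5 of 17 at least 2-fold higher, among them mrc1 (0.66 and 3.85), flt4 (1.08 and 3.73) and stab1 (0.71 and 2.62), all under 5 FPKM. lyve1b was listed in the mutant library alone, at 3.79 FPKM. Of 24 VEGF and sprouting genes, 9 were at least 2-fold higher (median 0.80, percentile 100), including esm1 (15.6 and 59.4) and flt1 (3.91 and 14.2). Of 19 flow-responsive genes, 8 were (median 0.80, percentile 99.99), including dusp5 (log2 fold 1.85), plvapb (1.42), adm (0.69 and 3.39) and klf2a, a shear-induced transcription factor (7.05 and 18.1, count ratio 2.56), while klf4 was at 6.94 and 3.59. For junctions and the CCM complex the median was 0.43 (percentile 98.57), with 7 of 32 at least 2-fold higher: rasip1, cdh5, cldn5, tjp1, cgnl1, jam2a and ccm2. The CCM gene krit1 was at 6.59 and 6.82. Basement membrane and matrix genes had a median of 0.46 (percentile 99.44), with 6 of 32 at least 2-fold higher, among them loxl2a (6.32 and 24.3), a gene named fn1 (2.62 and 11.4, while its paralog was at 7.22 and 6.78), lama4 (4.26 and 14.2) and nid2 (log2 fold 1.25). col4a1, at 2.25 and 4.90 (count ratio 2.28, 1.81 to 2.89), stayed under the limit, with a log2 fold of 0.86 on FPKM + 1. Integrins and adhesion genes had a median of 0.55 (percentile 99.46), led by itga5 (2.06 and 10.6), itga8, itgb1 and tln1 (log2 folds 1.93, 1.05, 1.01 and 0.92). Of these lists, the junction list shares 5 members with the pan-endothelial list, the VEGF list 3 and the flow list 1. The venous and junction lists no longer stood apart under TMM (percentiles 78.04 and 94.98) or with a floor of 5 FPKM (58.18 and 80.69). The basement membrane list no longer did with that floor (95.29) or with symbols matched only as written (80.94).

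**Figure D3:**
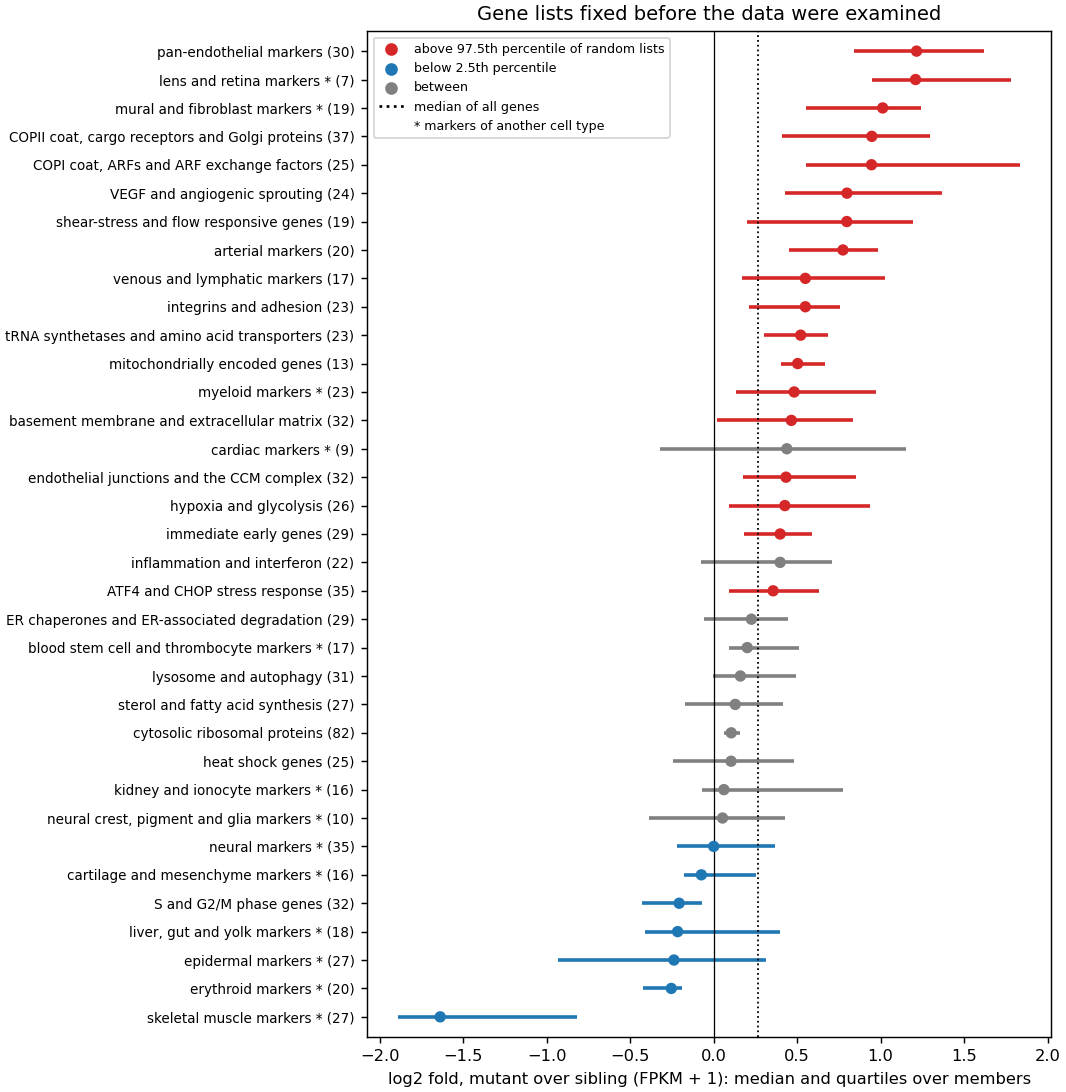
For each gene list reported here (number of members in brackets, an asterisk for markers of another cell type), the point gives the median log2 fold of the members, mutant over sibling, and the bar their quartiles; colour shows the place among random lists, and the dotted line the median of all genes. The pan-endothelial list has the highest median, 1.22, and the skeletal muscle list the lowest, -1.64.

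Markers of other cell types differed too, and not in one direction. Of 27 skeletal muscle genes, 19 were at least 2-fold lower in the mutant library and none at least 2-fold higher (median -1.64, percentile 0), including myl1 (146 and 31.6 FPKM), a gene named tnni2 (69.7 and 13.9), pvalb1 (119 and 29.7), actc1b (231 and 65.5) and the myosin heavy chain genes myhz2 (14.9 and 2.54) and myhz1.2 (12.2 and 2.22), whose near-identical copies divide reads. Erythroid genes had a median of -0.25 (percentile 0), with hbae1.2 at 159111 and 118855 FPKM and alas2, the first enzyme of erythroid heme synthesis, at 2592 and 2199. hbaa1, hbae5, hbae1.1 and hbae1.3 had log2 folds of -1.74, -0.52, -0.46 and -0.43. The globin genes also share reads, so their single values are uncertain. Epidermal genes had a median of -0.24 (percentile 0), with 6 of 27 at least 2-fold lower, among them aep1 (13.2 and 3.96), krt17 (9.59 and 2.94) and cyt1l (120 and 50.5), and 1, krt18b, higher (9.39 and 26.7). Liver, gut and yolk genes (median -0.22) and cartilage genes (-0.07, and 0.08 in TPM) lay below the 2.5th percentile, as did neural genes, whose median was -0.00 (0.15 in TPM). By the mean of the list, the liver (0.03, percentile 3.11) and cartilage (0.03, percentile 2.91) lists turned and did not stand apart. In these lists apoa1a, fgg, ambp and ela2 had log2 folds of 2.04, -0.80, 0.70 and 0.66, sox9, ucma, hapln1a and snorc 0.91, -0.79, 0.69 and -0.66, and stmn2, neurog1 and stmn1 -1.03, 0.78 and -0.68, with a further gene named stmn2 at -0.64.

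Mural and fibroblast genes were higher (median 1.01, percentile 100), with 10 of 19 at least 2-fold higher, among them pdgfra (2.56 and 12.3 FPKM), twist1b (2.06 and 10.5), twist1a (12.2 and 36.4) and foxc1b (7.17 and 21.4). Of 7 lens and retina genes, 5 were at least 2-fold higher from low levels (median 1.21), led by crybb1 (0.76 and 8.54) and cryba1b (0.20 and 5.01), with cryba2 and crybb1l2 at log2 folds of 1.23 and 1.21 and a count interval for cryba2 that held 1. A floor of 5 FPKM left 1 member of that list. Myeloid genes had a median of 0.48 (percentile 97.99), with 5 of 23 at least 2-fold higher, led by spi1 (log2 fold 1.64), a gene named mfap4 (1.58), plek (1.39) and ptprc (1.18), while lyz was at 582 and 823. By counts plek differed by a ratio of 1.72 (1.27 to 2.36), since its listed length differs. The myeloid list did not stand apart under 7 settings, among them TPM (percentile 96.57), TMM (96.56) and a floor of 0.1 FPKM (78.94). The blood stem cell, cardiac, kidney and neural crest lists did not stand apart, with medians of 0.20, 0.44, 0.06 and 0.05. In those lists at least 2-fold differences were seen for gfi1aa, thbs1 and myb (log2 folds 1.86, 1.48 and 1.17), hand2, gata5, gata4 and actc1a (1.74, 1.40, 1.15 and -1.04), and slc12a3, clcnk and cdh17 (1.58, 1.46 and 1.07) and atp1a1a.4 (40.9 and 83.0 FPKM). mpl, sox10, tyrp1 and dct had 0.69, 0.71, -0.87 and -0.85. foxd3 was listed in the mutant library alone, at 2.31 FPKM.

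Among general functions, S and G2/M phase genes had a median log2 fold of -0.21 (percentile 0), and none of 32 differed 2-fold. Beside the lists of this paragraph stand the erythroid, epidermal, skeletal muscle and pan-endothelial medians of -0.25, -0.24, -1.64 and 1.22. cdk1, the mitotic kinase, was at 158 and 94.8 FPKM, plk1 at 226 and 152 and kif23 at 75.9 and 51.5. ccnb2 was at 11.5 and 18.5, but with a count ratio of 1.31 (1.01 to 1.69). Hypoxia and glycolysis genes had a median of 0.43 (percentile 98.60), with hk2, slc2a1 and ldha among 6 of 26 at least 2-fold higher (log2 folds 1.45, 1.23 and 1.21) and a gene named aldoa lower (-1.24). That list did not stand apart with a pseudocount of 0.1 (97.35), by its mean (97.12), against unmatched random lists (96.06) or with symbols matched only as written (91.52). Mitochondrially encoded transcripts were higher by a median of 0.50, led by mt-nd5 (224 and 376), mt-nd4, mt-nd2 and mt-nd6 (0.70, 0.67 and 0.67). None of 13 was past 2-fold. All 13 counting intervals lay above 1, but so did those of 59 of 82 cytosolic ribosomal genes, whose median was below that of all genes. Immediate early genes had a median of 0.40 (percentile 99.89) with none past 2-fold, led by ier2a (137 and 271), with zfp36l1, mych and ccn1 at 0.97, 0.96 and 0.72. Against unmatched random lists neither the mitochondrial (95.73) nor the immediate early list (93.64) stood apart, nor did the immediate early list with symbols matched only as written (97.48). Heat shock genes had a median of 0.10 (percentile 18.91), with hsp70l at 965 and 866 FPKM, a gene named hspa4 at 200 and 114 and hspb8, hspd1 and hsp90aa1.1 at log2 folds of 1.22, 0.83 and -0.92. Of the 2 genes named hspa8, the abundant one was at 2316 and 2295 FPKM and the other had a log2 fold of 1.02. Lysosome and autophagy genes (0.16), sterol and fatty acid genes (0.13), cytosolic ribosomal proteins (0.11) and inflammation genes (0.40) did not stand apart, and the first 3 medians, with that of heat shock genes, fell below 0 once centred. In these lists sqstm1, an autophagy receptor, was at 24.8 and 55.2 FPKM and lamp2, lamp1b and wipi1 had log2 folds of 0.94, 0.89 and 0.73. By counts the ratio for wipi1 was 1.41 (1.19 to 1.69). hmgcs1, a sterol synthesis enzyme, was at 10.4 and 22.1, but with a count ratio of 1.35 (1.09 to 1.69) as its listed length differs, with fasn, mvk and idi1 at 0.73, -0.71 and 0.63. rpl7l1 and rps19bp1, which are in the ribosomal list by the form of their symbol and need not be ribosomal proteins, had 1.03 and 0.48. rpl36 and rpl5 had 0.40 and 0.26. Among inflammation genes irf7 was at 3.74 and 9.01, whereas cxcl8a was at 6.72 and 1.88, il6 at 3.35 and 0.95 and hamp at 5.32 and 1.96.

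Beside arf4b and aqp8, the 10 highest named genes were tmem71 (3.37 and 35.4 FPKM), klhl13, pdxdc1 (2.19 and 21.0), tm4sf18 (1.79 and 18.1, count ratio 7.23), matcap1 (0.77 and 10.9), lrrc59, an ER membrane protein (6.41 and 46.4), znf1070, listed in the mutant library alone at 5.15, and pvalb9 (0.25 and 6.53, from 1 expected count in the sibling). klhl13 was at 2.65 and 25.7 FPKM, but its counts differed by a ratio of 2.85 (1.65 to 5.16). The 10 lowest were nmrk2 (7.54 and 0.35), and2, a fin fold actinodin (9.73 and 0.87), tnni2, myl1, myhz2, myhz1.2, myhz1.3 (log2 fold -2.03), myl11 (126 and 31.3), pvalb1 and myl13 (6.89 and 1.06), most of them skeletal muscle genes. A further 8 loci without a gene name stood above the lowest of the 10 highest genes, and 4 below the highest of the 10 lowest.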

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

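The alternatives without the 10 highest genes, with genes listed in both tables, and with the listed symbol alone were chosen after the data were seen. No paired analysis was possible because there is 1 library per group, and for the same reason no replicate could be left out and no other split of the samples exists. Of 168 named genes besides gbf1, 109 were past 2-fold, 79 of them under every alternative tried, and none that was past 2-fold reversed. Most of these genes were picked for large log2 folds in the same libraries, so the lack of reversals says little. Of the 25 lists that stood apart, 13 kept both that place and the sign of the median under every setting tried. Of the other 11 lists, 4 stood apart under a setting: sterol and kidney genes with a mean FPKM of at least 0.1, neural crest genes with TMM and median of ratios, and ribosomal genes against unmatched lists. The counts of genes higher and lower were 321 and 186 once centred, 378 and 169 with TMM, 367 and 175 with median-of-ratios scaling, 387 and 49 with an FPKM of at least 10, 1205 and 292 with no filter, 2039 and 272 at 1.5-fold, and 51 and 11 at 4-fold, since these settings move the centre, the genes counted or the threshold. Without the 10 highest genes they were 495 and 143. They stayed within 1.5 times with TPM (948 and 72), an FPKM of at least 1 (939 and 125), pseudocounts of 0.1 (883 and 115) and 0.5 (779 and 106), and genes that both libraries list (663 and 90).

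These lists no longer stood apart, and the cause was not tested. They kept their direction, except that the ATF4 and CHOP median was 0.00 with median of ratios. ATF4 and CHOP: TMM 0.013, unmatched random lists 0.356. Venous and lymphatic: TMM 0.151, median of ratios 0.139, mean FPKM of at least 5 0.318, genes that both libraries list 0.528, listed symbol alone 0.55. Junctions: TPM 0.55, TMM 0.136, median of ratios 0.124, pseudocount 0.1 0.457, FPKM of at least 5 0.325. Basement membrane: FPKM of at least 5 0.389, listed symbol alone 0.345. Hypoxia: pseudocount 0.1 0.435, unmatched lists 0.426, mean of the list 0.439, listed symbol alone 0.44. Immediate early: unmatched lists 0.398, listed symbol alone 0.337. Myeloid: TPM 0.581, TMM 0.218, median of ratios 0.205, pseudocounts 0.1 and 0.5 both 0.502, without the 10 highest genes 0.327, FPKM of at least 0.1 0.312. Mitochondrial: unmatched lists 0.503. Lens and retina: FPKM of at least 5 0.768, with 1 member left. The sign turned for neural genes (TPM 0.15, FPKM of at least 5 0.014, mean of the list 0.033), liver genes (mean 0.025) and cartilage genes (TPM 0.076, mean 0.029), and the cause was not tested.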

Other observations

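The tests of the share of globin reads, of more cells of every other type alike, of erythroid cells and of differing shares of each cell type were chosen after the result was seen, and so were the gene families of the next sentences. Several families for entry into the ER and for Golgi structure had medians above that of all genes in the mutant library, though in none of them were most members past 2-fold. Of the 17 genes of the translocon, the signal recognition particle and its receptors, 7 were at least 2-fold higher, with a median log2 fold of 0.87 (percentile 100 of random lists). Of the 2 genes named sec61a1, the pore of the translocon, the less abundant (8.64 and 29.0 FPKM) had 1.64. The abundant one (126 and 175 FPKM) had 0.47. srprb had 1.47. Golgins, taken by symbol, had a median of 0.99 (5 of 10 past 2-fold, golga3 1.56). The Yip family had 1.02 (4 of 8, yif1a 1.82) and the COG complex 0.84 (3 of 8, cog6 1.56). The p24 cargo receptors had 0.76 (1 of 9, tmed3 at 5.70 and 17.9 FPKM) and the oligosaccharyltransferase 0.65 (2 of 9, krtcap2 1.43). Apart from the abundant sec61a1, the genes named are the highest of their family. Bootstrap intervals over members held the median of all genes, 0.27, for the COG complex (0.21 to 1.53), the p24 receptors (-0.03 to 0.93) and the oligosaccharyltransferase (0.25 to 1.04). The pan-endothelial, mural and skeletal muscle medians of 1.22, 1.01 and -1.64 stand beside these families too. Some golgins, Yip and p24 genes are also in the COPII and Golgi list.

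Most other complexes stood near the median of all genes, 0.27, and respiratory complex I and the V-ATPase below it. The families were matched by symbol, so they can hold genes outside the complex named. The median was 0.26 for the ER membrane complex, whose 2 genes named emc4 were at 1.65 and -2.15, and 0.31 for the exocyst. It was 0.25 for genes named vps or chmp, which include retromer and ESCRT, 0.14 for the proteasome and 0.23 for the mitochondrial ribosome. It was 0.09 for complex I (percentile 4.77), 0.17 for splicing factors, 0.25 for RNA polymerase II and its general factors, 0.20 for the chaperonin and -0.08 for the V-ATPase (percentile 0.14). The glycosylation genes named alg had 0.48 (percentile 87.24), with alg5 at 2.29 and alg2 at 1.96.

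The cause of the higher COPI coat genes was not settled, and no test here addresses what the gbf1 allele does, so a biological explanation was not tested. A lower share of globin reads would raise every other gene by one factor, and the COPI median exceeds the factor of the 10 highest genes by 0.77 (bootstrap interval over members 0.43 to 1.58). Handling stress predicts a shift of immediate early or heat shock genes by over 0.5, and the larger of their medians lay 0.13 above all genes (-0.03 to 0.19), though the immediate early list stood at percentile 99.89, and a general rise of housekeeping genes is argued against by the highest of 7 family medians, which lay -0.02 from all genes (-0.10 to 0.15). A higher share of endothelial cells in the mutant sort was not told apart from a difference in expression. The planned rule asked the median of the coat subunits to exceed the pan-endothelial median by more than the interquartile range of that list. It did so by 0.62 against a range of 0.78, and 7 of 9 coat genes lay above the pan-endothelial median. That range is a spread among members and not the precision of the difference, so the rule leaves the question open. arf4b, with a log2 fold of 5.29, lies above the pan-endothelial median of 1.22 and above sox18, the highest member of that list, at 2.48. It is 1 gene, picked for the largest difference, so it does not decide the cause for the coat genes.

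The median of the higher pan-endothelial markers exceeds the factor of the 10 highest genes by 1.04 (0.90 to 1.3), which argues against a lower share of globin reads as the whole cause. More cells of other types in the sibling library cannot be told apart from the rest: the planned test asked for at least 3 of the 12 other lists to lie over 0.5 above all genes, and 2 did, while 8 lay below all genes. For more cells of every other type alike, the mural and skeletal muscle medians were compared, which lie 2.65 apart with separate quartile ranges. These 2 lists were picked after their medians were seen, and lie at or near the ends of the 12. Their gap therefore does not decide the question. Erythroid dilution as the whole cause would raise the other lists alike, yet 8 of 12 have an upper quartile below the lower quartile of the pan-endothelial list. A contribution from it is not excluded, as the erythroid median was -0.25. A share of each cell type that differs between the 2 sorts cannot be told apart from expression with 1 library per group. Of the 12 lists, 1 lies within 0.1 of all genes. The rule could only have argued against differing shares, had all 12 done so, and that count therefore decides nothing.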
